A study of Mus musculus with 6 samples.

How the data were processed

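RNA from primary mouse embryonic fibroblasts was measured on 6 one-colour Agilent expression arrays: 2 of untreated cells (0 h), 2 after 2 h and 2 after 4 h in 1 mM H2O2. Per the labels, the cells grew in DMEM with serum, RNA was extracted with Trizol, the label was Cy3, and the 2 arrays of a time point came from 2 independent experiments; what made them independent (embryos, cultures or days) is not given in the sources used here. Per the file headers, the authors scanned the arrays with a G2505B scanner and extracted the signals with Feature Extraction 9.5.3.1 under the protocol GE1-v5_95_Feb07. The deposited scanner files hold fluorescence intensity for each spot, raw and background-corrected, and the deposited value table also holds intensity, on a linear scale. That table was checked against the scanner files and equals their processed signal within 0.0005.

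The processed signal was taken to log2, and each array's 75th percentile over its 43379 non-control spots (of 45018) was subtracted, so changes are log2 values computed here from the deposited intensity. Spots with an outlier flag were left out (between 99 and 149 per array), and the 10 spots of each of 245 repeated probes were averaged. The 41174 probes were named by their accession in a RefSeq gene table (22951 probes), by a name in the file that is a symbol of that table (6659) or an older symbol (3109), or by the name in the file (8455). Of 27670 names 8914 had 2 or more probes, and the probe with the highest mean stood for the gene. The 17164 genes that were well above background on both arrays of at least 1 group were tested. The genome build of the probe coordinates is not given in the sources used here, so no coordinate is printed, and positions served only for neighbouring genes and lengths from the gene table.

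As a measure of depth, the 75th percentile of the signal was 826 and 883 (untreated replicates 1 and 2), 675 and 677 (2 h), and 674 and 754 (4 h). The share of spots well above background was 61.5% and 65.7%, 60.9% and 68.0%, and 57.3% and 60.0%. No spot was saturated, and with 2 arrays per group the number of arrays limits the precision.

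Changes at 2 h and 4 h against untreated cells, and 4 h against 2 h, were tested in 1 model of all 6 arrays with limma 3.58.1 in R 4.3.3 (files read with the data.table package, version 1.17.8), with moderated variances (3 residual and 1.64 prior degrees of freedom), and p-values were adjusted over all genes of a comparison with the Benjamini-Hochberg method. A gene rose or fell when the adjusted p was under 0.05. Gene lists were tested against all other genes with camera at a preset correlation between genes of 0.01, for 39 lists with at least 4 measured members, adjusted over the lists of a comparison. Camera with the correlation estimated for each list, and fry, were alternatives. With an estimated correlation, camera takes its p-values from the 3 residual degrees of freedom of the fit, so it has little power here. A call lost under it does not by itself show that correlation between genes made the call. The PValue of fry tests whether the genes of a set move on balance one way. Its PValue.Mixed tests whether they move in either direction, and neither compares them with other genes. Where a gene was not well above background on either array of 1 of the groups, its fold is given as "at least", from the group mean on the side above background and, on the other side, from each array's lowest signal well above background or the gene's own value, whichever was larger, and no fold is given where both groups lay below it.

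The groups, the tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The text draws its genes from 3 sources. The first is the 8 largest rises and 8 largest falls at each time (5 and 5 between times) among genes past the test whose treated arrays lay beyond both untreated ones, with bounded genes apart (up to 3 each way). Only genes with a gene symbol were ranked, so those with a clone, Riken, Gm, LOC or accession name were left out. The second is 18 genes chosen in advance, whatever their result. The third is up to 4 members of each list past its test, with the largest change in the list's direction. From these the text prints a subset chosen before any alternative had been seen. Hspa1b, one of the 18, has no probe of its own name and so has no value here. Hspa1a is given as a member of the heat shock list, from the brightest of its 4 probes. The lists were targets of Nrf2, p53, ATF4, FoxO, NF-kB, interferon, SRF and YAP, and TGF-beta and BMP; other antioxidant enzymes, immediate early, MAP kinase feedback, heat shock, ER chaperone, metal response, DNA replication, mitosis, replication histone, DNA repair, matrix, cholesterol, hypoxia, respiratory chain, ribosomal protein, ribosome biogenesis, proteasome, autophagy, apoptosis, circadian and splicing genes; markers of 9 cell types; and genes named Zfp.

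Arrays with the same replicate number shared a slide and a scan. Deviations from the group means correlated across genes, which are not independent replicates, with r = 0.243 (0 h and 2 h), 0.196 (0 h and 4 h) and 0.241 (2 h and 4 h), and since only 2 numbers exist the arrays were not called paired; slide values are given as a block and within each slide. All arrays were scanned on the same day, so a block by scan date was not run.

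Alternatives were quantile normalization, median centring, no scaling, normexp background correction (offset 50) with the 75th percentile or quantile, the deposited table, no filter or a stricter filter on dim probes, outlier spots kept, the mean of a gene's probes or every probe, the slide as a block, only the 4 arrays compared, a trend and robust prior, other thresholds, other list tests, and each array left out in turn, where the lone array of a group is assumed to vary like the others. Scaling to the mean of 7 bright spike-in control probes was chosen after seeing the data; it assumes equal amounts of control RNA on all arrays, and the amount added is not given in the sources used here. The model was also tested on simulated data, in which 19.4%, 83.6% and 83.3% of genes changed by 0.5, 1 and 2 were recovered, with 3 false calls among 127. A list of 30 genes shifted by 0.3 had an adjusted p of 4.95e-25 in camera against 0.849 for an unshifted list. The simulated genes varied independently and few were changed, so this does not test the list calls where genes are correlated or many change.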

Results

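Transcript levels were measured in primary mouse embryonic fibroblasts, cells grown out of mouse embryos, before and after exposure to 1 mM hydrogen peroxide (H2O2), an oxidant. There were 3 groups of 2 arrays each: untreated cells (0 h), cells after 2 h and cells after 4 h in H2O2. The labels give the 2 arrays of a group as independent experiments. The p-values and standard errors below rest on the spread between such experiments, pooled over the 3 groups and moderated across genes. Of 43379 non-control spots, between 57.3% and 68.0% lay well above background on each array, no spot was saturated, and 17164 genes were tested. Replicate arrays correlated across genes with r = 0.992 (untreated), 0.994 (2 h) and 0.994 (4 h), and the number of arrays limits the precision. Values are log2 changes with their standard error (SE, n = 2 arrays per group) and limma p-values adjusted by the Benjamini-Hochberg method, and gene lists were tested with camera. The median of all genes moved by 0.12 at 2 h, 0.07 at 4 h and -0.08 between 2 h and 4 h, so the shift of a list is given relative to that median. Both slides held 1 array of each time point, and each time point had the same position on both slides, so slide position and time cannot be told apart. No untreated cells were measured at 2 h or 4 h, so effects of time in culture and handling cannot be told apart from those of H2O2.

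The first comparison asked which transcripts changed within 2 h in H2O2. Among genes with a gene symbol (no clone, Riken, Gm, LOC or accession name) above background on all 4 arrays the largest rise was in Slc5a2, a renal glucose transporter (log2 change 6.53 ± 0.15, 92.3-fold, adjusted p = 0.000112). It was followed by Rasgef1a, an exchange factor for Ras-family proteins (5.72 ± 0.06, adjusted p = 4.68e-05, with 3.89 from its other probe). Gzmm, a granzyme of cytotoxic lymphocytes, rose by 5.57 ± 0.12, and Lman1l, a lectin-like protein of the secretory pathway, by 4.93 ± 0.09. Transcripts not well above background in untreated cells rose at least 75.7-fold for Vil1 (villin, an actin-bundling protein of microvilli), at least 54.6-fold for Ampd1 (the muscle AMP deaminase) and at least 42.0-fold for Stra8 (a gene of meiotic entry in germ cells). Among genes with a gene symbol above background on all 4 arrays the largest falls were in Zxdc, a zinc finger protein (-2.67 ± 0.06), and Txnip, which binds and inhibits thioredoxin (-2.66 ± 0.05, adjusted p = 9.66e-05). The Zxdc fall rests on 1 of 2 probes, since its other probe, also above background on all 6 arrays, gave -0.02. Tube1 (epsilon-tubulin) fell by 2.44, Trim13 (a ubiquitin ligase) by 2.44 and Lipt1 (a lipoyltransferase) by 2.29. Xist, the RNA of X-chromosome inactivation, fell at least 13.0-fold to below background, while its 3 other probes were at background on all arrays.

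Transcripts of the oxidative stress regulator Nrf2 shifted upward at 2 h (median 0.25 above all genes, adjusted p = 0.000369, 0.15 above with no filter on dim probes, own median -0.08 after spike-in scaling). Of its 27 targets 16 rose, 1 fell and 10 did not pass (23 rose and 1 fell adjusted over the list alone), and adjusted p = 0.327 with an estimated correlation. Hmox1, which encodes the heme-degrading enzyme heme oxygenase, rose 5.60-fold (2.48 ± 0.08, adjusted p = 0.000189, 2.47 and 2.50 on slides 1 and 2). The cystine transporter Slc7a11 rose by 1.62 ± 0.08 on its brightest probe and had 0.52 on another, sulfiredoxin Srxn1 rose by 1.15 ± 0.08 (0.67 and 0.62 on 2 other probes) and thioredoxin reductase Txnrd1 by 0.63 ± 0.08. Nqo1, a quinone reductase, rose by 0.27 ± 0.06 (adjusted p = 0.0215). Its change was -0.07 with no scaling and -0.18 after spike-in scaling, there past the test in the other direction (adjusted p = 0.0440). Gclm, a subunit of the rate-limiting enzyme of glutathione synthesis, did not pass (0.42 ± 0.14, adjusted p = 0.0703, and -0.03 after spike-in scaling). The metal-binding protein gene Mt1 did not pass either (0.28 ± 0.14, adjusted p = 0.163, 0.0371 with the slide as a block, -0.05 with no scaling, -0.17 after spike-in scaling and -0.20 on another probe). The Nrf2 list's own median was 0.34 on slide 1 and 0.36 on slide 2.

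Targets of the tumour suppressor p53 rose together at 2 h (median 0.62 above all genes, adjusted p = 2.81e-06), with 25 of 31 up, 3 down and 3 not passing (26 and 3 adjusted over the list alone), and adjusted p = 0.126 with an estimated correlation. Gdf15, a stress-induced secreted factor, rose by 2.88 ± 0.10, and Mdm2, the ubiquitin ligase that marks p53 for degradation, by 2.39 ± 0.09. Pmaip1, which promotes cell death at mitochondria, rose by 1.94 ± 0.06, the cell cycle inhibitor gene Cdkn1a by 1.69 ± 0.10 and Ccng1 (cyclin G) by 0.66 ± 0.06. Immediate early genes, transcription factors and regulators induced without new protein synthesis, stood 0.72 above all genes (adjusted p = 1.43e-07), with 22 of 25 up and none down (also 22 up adjusted over the list alone), and adjusted p = 0.126 with an estimated correlation. Among these Fosb rose by 3.17 ± 0.22, Atf3 by 2.61 ± 0.06, the antiproliferative gene Btg2 by 1.36 ± 0.08 (2.05 on another probe) and Junb by 1.33 ± 0.06. Fos (0.61 ± 0.09) and Egr1 (0.62 ± 0.06) had smaller rises. Feedback regulators and ligands of the MAP kinase pathway stood 0.63 above all genes (9 of 14 up and 1 down, both also adjusted over the list alone, adjusted p = 0.0184), with adjusted p = 0.415 with an estimated correlation, and 0.31 above with no filter on dim probes. The growth factor gene Areg rose at least 8.54-fold from below background, its relative Ereg rose by 1.70 ± 0.11 and Phlda1, a pleckstrin-like regulator of survival signalling, by 1.5 ± 0.06. The lists' own medians on slides 1 and 2 were 0.72 and 0.77 (p53), 0.85 and 0.83 (immediate early) and 0.77 and 0.75 (MAP kinase).

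Other transcripts fell at 2 h. The 277 zinc finger genes named Zfp, many of which encode DNA-binding repressors, had a median 0.54 below all genes, with 148 down, 23 up and 106 not passing (154 and 30 adjusted over the list alone, adjusted p = 3.29e-15). This was the only list of the 39 that passed at 2 h with its correlation estimated (adjusted p = 0.0406), a test with little power at 3 residual degrees of freedom. Zfp111 fell by 2.07 ± 0.12, and Zfp454 and Zfp879 fell at least 2.10-fold and at least 1.29-fold to below background. Interferon response genes stood 0.52 below all genes (12 of 22 down, 1 up, 9 not passing; 13 and 1 adjusted over the list alone; adjusted p = 5.25e-06), with adjusted p = 0.327 with an estimated correlation. The interferon signalling factors Stat2 and Irf1 fell by 1.25 ± 0.06 and 1.21 ± 0.06, and the interferon-induced gene Rtp4 by 0.79 ± 0.07. Mitosis genes stood 0.21 below all genes (7 of 28 down, 1 up, the same counts adjusted over the list alone, adjusted p = 0.0123), with adjusted p = 0.482 with an estimated correlation. The proliferation marker Mki67 fell by 0.52, the centromere protein gene Cenpf by 0.39 and the mitotic kinase gene Aurka by 0.38. Targets of FoxO factors stood 0.53 below all genes (9 of 16 down and 4 up, 9 and 5 adjusted over the list alone, adjusted p = 0.0165), with adjusted p = 0.327 with an estimated correlation. The FoxO call was also lost after quantile normalization (0.0886, shift -0.47), median centring (0.113, -0.53), no scaling (0.199, -0.53), normexp with quantile (0.0626, -0.41) and spike-in scaling (0.399, -0.53). Fbxo32, a muscle atrophy ubiquitin ligase, fell by 1.54 ± 0.20 and Ccng2, a cyclin of arrested cells, by 0.87 ± 0.06. The shift was -0.35 for Zfp and -0.33 for interferon genes after normexp with quantile. The lists' own medians on slides 1 and 2 were -0.40 and -0.42 (Zfp), -0.50 and -0.33 (interferon), -0.10 and -0.10 (mitosis) and -0.44 and -0.41 (FoxO).

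Several sets of abundant transcripts passed at 2 h only under some scalings. Ribosomal protein genes stood 0.25 above all genes (29 of 37 up, none down, 36 up adjusted over the list alone, adjusted p = 6.70e-06), with adjusted p = 0.490 with an estimated correlation. With the preset correlation the adjusted p was 0.401 after quantile normalization and 0.199 after spike-in scaling, where their own median was -0.08. Rpl6 rose by 0.43 ± 0.06 and Rps20 by 0.43 ± 0.06, but after spike-in scaling they had -0.02 and -0.03, and another probe of Rps20 had 0.09. Proteasome genes stood 0.18 above all genes (19 of 31 up, none down, 25 up adjusted over the list alone, adjusted p = 0.000189), with adjusted p = 0.490 with an estimated correlation, adjusted p = 0.105 with no scaling and their own median at -0.04 there. Psmb2 of this list rose by 0.43 ± 0.06 (-0.02 after spike-in scaling). Respiratory chain genes stood 0.18 above all genes (20 of 36 up, none down, 21 up adjusted over the list alone, adjusted p = 0.000369), with adjusted p = 0.482 with an estimated correlation, adjusted p = 0.227 with no scaling and their own median at -0.04 there. Uqcrb rose by 0.44 ± 0.07 and Cox6b1 by 0.38 ± 0.06, with -0.01 and -0.08 after spike-in scaling. Other antioxidant enzymes stood 0.14 above all genes (8 of 23 up, none down, 6 up adjusted over the list alone, adjusted p = 0.0123), with adjusted p = 0.523 with an estimated correlation. Their own median was -0.08 with no scaling and -0.20 after spike-in scaling, where camera put the list on the lower side (adjusted p = 0.874). The superoxide dismutase gene Sod1 rose by 0.38 ± 0.09 and the peroxiredoxin gene Prdx6 by 0.38 ± 0.05, both at -0.07 after spike-in scaling. The 2 dimmer probes of Sod1 gave -0.32 and -0.39. Calls were also lost after quantile normalization for proteasome (0.0501), respiratory chain (0.111) and antioxidant genes (0.0979), and after normexp with quantile for ribosomal (0.222), respiratory chain (0.110) and antioxidant genes (0.109). They were lost after spike-in scaling for proteasome (0.848) and respiratory chain genes (0.963), and for antioxidant genes after median centring (0.152) and with no scaling (0.584). The shifts stayed at 0.181, 0.179 and 0.137 there, since such a scaling moves all genes alike. For ribosomal, proteasome, respiratory chain and antioxidant genes in turn the shifts were 0.03, 0.07, 0.06 and 0.07 after quantile normalization, 0.03, 0.07, 0.06 and 0.06 after normexp with quantile, and 0.16, 0.09, 0.08 and 0.04 with no filter on dim probes. Slides 1 and 2 gave own medians of 0.34 and 0.40 (ribosomal), 0.28 and 0.32 (proteasome), 0.26 and 0.33 (respiratory chain) and 0.25 and 0.29 (antioxidant).

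A further 4 lists passed at 2 h. Heat shock chaperones stood 0.24 above all genes (10 of 19 up, none down, 12 up adjusted over the list alone, adjusted p = 0.0102), with adjusted p = 0.482 with an estimated correlation and 0.131 with no scaling, and an own median of -0.09 after spike-in scaling. The inducible chaperone gene Hspa1a rose by 1.13 ± 0.06 and its cofactor gene Bag3 by 0.80 ± 0.08, while Dnajb1 did not pass (-0.18 ± 0.08, 0.05 on another probe, adjusted p = 0.155, 0.0456 with the slide as a block). Autophagy and lysosome genes stood 0.11 above all genes (9 of 21 up, none down, 10 up adjusted over the list alone, adjusted p = 0.0223), with adjusted p = 0.482 with an estimated correlation and an own median of -0.11 with no scaling. The autophagosome gene Gabarapl1 rose by 0.68 ± 0.05 and the cargo receptor gene Sqstm1 by 0.58 ± 0.10. Hypoxia and glycolysis genes stood 0.15 above all genes (9 of 23 up, 1 down, 12 and 1 adjusted over the list alone, adjusted p = 0.0399), with adjusted p = 0.448 with an estimated correlation and an own median of -0.07 with no scaling. The angiogenic factor gene Vegfa rose by 0.84 ± 0.05 (1.38 on another probe). Extracellular matrix genes stood 0.11 above all genes (7 of 22 up, none down, 5 up adjusted over the list alone, adjusted p = 0.0184), with adjusted p = 0.482 with an estimated correlation, and their shift was -0.05 after quantile normalization and -0.06 after normexp with quantile. Col1a1, the main fibrillar collagen chain, rose by 0.33 ± 0.06 (0.12 and 0.09 on 2 other probes), and had -0.04 after quantile normalization, -0.01 with no scaling, -0.03 after normexp with quantile and -0.13 after spike-in scaling. For heat shock, autophagy, hypoxia and matrix genes in turn, the adjusted p was 0.101, 0.334, 0.177 and 0.610 after quantile normalization, 0.109, 0.305, 0.194 and 0.484 after normexp with quantile, and 0.260, 0.963, 0.861 and 0.528 after spike-in scaling. For the last 3 of these it was 0.187, 0.138 and 0.329 after median centring, 0.514, 0.514 and 0.984 with no scaling, and 0.0667, 0.0843 and 0.112 after normexp with the 75th percentile. For matrix genes it was 0.277 with the mean of a gene's probes and 0.0571 with every probe. Median centring and no scaling left the shifts of autophagy (0.115), hypoxia (0.148) and matrix genes (0.108) unchanged. Shifts of heat shock, autophagy and hypoxia genes were 0.11, 0.03 and 0.06 after quantile normalization, 0.11, 0.02 and 0.06 after normexp with quantile, and 0.15, 0.02 and 0.05 with no filter on dim probes, where that of matrix genes was 0.01. After normexp with the 75th percentile they were 0.09 for hypoxia and 0.07 for matrix genes, and autophagy genes had 0.17 with the mean of a gene's probes. Matrix genes ranged from 0.07 (without untreated replicate 2 or 2 h replicate 1) to 0.17 (without 2 h replicate 2). Without untreated replicate 2 the adjusted p was 0.0614 for matrix, 0.0693 for hypoxia and 0.0626 for autophagy genes, and without 2 h replicate 1 it was 0.0584, 0.0895 and 0.0761. For hypoxia genes it was also 0.0669 without untreated replicate 1 and 0.0504 without either 4 h array. Own medians on slides 1 and 2 were 0.33 and 0.37 (heat shock), 0.25 and 0.25 (autophagy), 0.25 and 0.30 (hypoxia) and 0.22 and 0.22 (matrix).

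Among markers of other cell types that a fibroblast culture could hold, endothelial markers rose at 2 h (5 of 8 up and none down, the same counts adjusted over the list alone, median 1.41 above all genes, adjusted p = 0.0102), with adjusted p = 0.327 with an estimated correlation. Their own median was 1.37 on slide 1 and 1.69 on slide 2, and the shift was 0.42 when only genes above background on all arrays were tested (adjusted p = 0.162) and 0.41 with only such members (0.199). It was 0.67 with no filter on dim probes, 0.55 after normexp with the 75th percentile and 0.37 after normexp with quantile. The guidance receptor gene Robo4 rose at least 5.43-fold and the adhesion gene Pecam1 at least 2.26-fold from below background, and the clotting factor gene Vwf rose by 1.81 ± 0.07. The tight junction gene Cldn5 (3.77 ± 0.60) was above background on 1 of 2 untreated arrays. Markers of macrophages (adjusted p = 0.821), epithelium (0.128), neural cells (0.3), muscle (0.128), erythroid cells (0.0637), adipocytes (0.245), bone and cartilage (0.621) and fibroblasts themselves (0.635) did not pass in camera at 2 h.

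Of the other genes chosen in advance, the inflammatory genes Il6 and Ccl2 rose at 2 h by 0.49 ± 0.06 and 0.51 ± 0.06, with 0.16 and 0.18 with no scaling and 0.04 and 0.06 after spike-in scaling, where neither passed. Trib3, a pseudokinase of the amino acid response, fell by 0.37 ± 0.07. The stress factor gene Ddit3 did not pass (-0.32 ± 0.10, adjusted p = 0.0682, 0.0210 with the slide as a block). In all, 4089 genes rose and 2635 fell at 2 h, 1252 and 587 of them at least 2-fold, and 480 of those that rose were not above background in untreated cells. All 6724 moved the same way on both slides, as any gene past this test must with 2 arrays per group, so this is no separate check. With the slide as a block 5781 rose and 3295 fell. Within slide 1, 1443 genes were at least 2-fold higher and 778 lower, and within slide 2, 1480 and 644. The split of rises and falls depended on the scaling, with 2579 and 3262 after quantile normalization, 1844 and 3824 after median centring, and 1529 and 5707 with no scaling. It was 2712 and 3420 after normexp with quantile, and 1459 and 9196 after spike-in scaling. Leaving out 1 array gave 3884 calls (without untreated replicate 1), 3655 (untreated replicate 2), 3711 (2 h replicate 1) and 3600 (2 h replicate 2). After normexp with the 75th percentile 1566 were called. Named genes lost the call with no scaling (Ccl2, Col1a1, Cox6b1, Egr1, Fos, Il6, Nqo1, Prdx6, Psmb2, Rpl6, Rps20, Sod1, Sqstm1 and Uqcrb) and after median centring (these other than Ccl2, Egr1, Fos and Il6). After spike-in scaling all of these and Txnrd1 lost it, after quantile normalization Col1a1, Nqo1, Rpl6, Rps20 and Sod1 did, and after normexp with quantile the same but Nqo1. With no filter on dim probes Col1a1, Nqo1, Sod1 and Trib3 lost it, and with the mean of a gene's probes Col1a1, Prdx6 and Sod1 did. After normexp with the 75th percentile the calls of Areg, Aurka, Cenpf, Cldn5, Mki67, Pecam1, Robo4, Trib3, Txnrd1, Xist, Zfp454 and Zfp879 were lost, and so were those of the genes lost with no scaling other than Egr1. With 1 array left out, Aurka, Cenpf, Cldn5, Col1a1, Cox6b1, Nqo1, Prdx6, Psmb2, Rpl6, Sod1, Sqstm1, Trib3, Uqcrb or Zfp879 no longer passed. With the slide as a block all 17 lists stayed past the test, MAP kinase feedback with the highest adjusted p (0.0430).

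The second comparison asked which transcripts differed from untreated cells after 4 h in H2O2. Slc5a2 remained 66.5-fold higher (6.06 ± 0.15, adjusted p = 0.000158), and Lman1l (5.54 ± 0.09), Gzmm (5.39 ± 0.12), Rasgef1a (5.01 ± 0.06) and the collagen gene Col20a1 (5.49 ± 0.08) rose. Gtf2a1l, a germ cell form of a general transcription factor, rose at least 55.4-fold from below background, Vil1 at least 40.4-fold and Ampd1 at least 30.9-fold. Among genes with a gene symbol above background on all 4 arrays compared, the largest falls were in Sapcd2, a regulator of spindle orientation (-2.25 ± 0.11, adjusted p = 0.000514), and the mismatch repair gene Pms1 (-2.17 ± 0.12). Brca2, which acts in homologous recombination, fell by 2.03 ± 0.09 and Depdc1b, which links loss of adhesion to mitotic entry, by 1.99 ± 0.09. Xist fell at least 8.30-fold to below background.

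Mitosis, DNA replication, replication histone and DNA repair genes lay below all genes as lists at 4 h, but only among mitosis genes did most members fall. Mitosis genes stood 0.66 below all genes (24 of 28 down, 1 up, 25 and 1 adjusted over the list alone, adjusted p = 1.02e-10), with adjusted p = 0.268 with an estimated correlation. The mitotic kinase gene Plk1 fell by 1.48 ± 0.06, Mki67 by 1.41 ± 0.06, Cenpf by 1.28 ± 0.06 and Aurka by 1.05 ± 0.05. DNA replication genes stood 0.25 below all genes (11 of 30 down, 2 up, the same adjusted over the list alone, adjusted p = 0.00157), with adjusted p = 0.268 with an estimated correlation. Their shift was -0.43 after normexp with the 75th percentile and -0.41 with no filter on dim probes. The histone chaperone gene Chaf1a fell by 0.73 ± 0.08, the polymerase gene Pole by 0.72 ± 0.06 and the helicase factor gene Cdc45 by 0.68 ± 0.09. The mean of the probes of Pole gave 0.10, since its other probe was at background on all arrays. Replication-dependent histone genes stood 0.35 below all genes (5 of 22 down, none up, the same adjusted over the list alone, adjusted p = 0.00753), with adjusted p = 0.582 with an estimated correlation and 0.0544 without 4 h replicate 2, and a shift of -0.23 without untreated replicate 1. The linker histone genes H1f5 and H1f4 fell by 1.47 ± 0.12 and 0.96 ± 0.10. DNA repair genes stood 0.38 below all genes (12 of 24 down, 2 up, 13 and 2 adjusted over the list alone, adjusted p = 0.00237), with adjusted p = 0.268 with an estimated correlation. Besides Brca2, the base excision gene Mutyh fell by 1.12 ± 0.07 (-0.49 on another probe) and Brca1 by 1.06 ± 0.06. Own medians on slides 1 and 2 were -0.59 and -0.61 (mitosis), -0.15 and -0.22 (replication), -0.30 and -0.23 (histones) and -0.24 and -0.37 (repair).

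Targets of p53 and Nrf2 stayed high at 4 h, and immediate early genes stood above all genes by less than at 2 h. Targets of p53 stood 1.05 above all genes (27 of 31 up, 2 down, 28 and 2 adjusted over the list alone, adjusted p = 8.10e-10), with adjusted p = 0.190 with an estimated correlation. Gdf15 rose by 3.05 ± 0.10, Pmaip1 by 2.54 ± 0.06, Mdm2 by 2.35 ± 0.09, Cdkn1a by 2.12 ± 0.10 and Ccng1 by 1.05 ± 0.06. The costimulatory ligand gene Cd80 rose by 2.75 ± 0.05 on its brightest probe and 1.24 on the other. Nrf2 targets stood 0.44 above all genes (22 of 27 up, 1 down, 23 and 1 adjusted over the list alone, adjusted p = 8.36e-06), with adjusted p = 0.268 with an estimated correlation. Hmox1 rose by 2.41 ± 0.08, Slc7a11 by 1.5 ± 0.08 (0.96 and 0.42 on other probes), Srxn1 by 1.40 ± 0.08, Txnrd1 by 0.86 ± 0.08, Gclm by 0.65 ± 0.14 and Nqo1 by 0.37 ± 0.06. Osgin1, an oxidative stress-induced growth inhibitor, rose by 1.37 ± 0.10 (0.50 on another probe). Immediate early genes stood 0.38 above all genes (15 of 25 up, 2 down, 16 and 2 adjusted over the list alone, adjusted p = 0.00359), with adjusted p = 0.268 with an estimated correlation and 0.0539 after normexp with the 75th percentile. Fosl1, a Fos relative, rose by 1.73 ± 0.08, Btg2 by 1.25 ± 0.08, Fosb by 1.01 ± 0.22, Fos by 0.93 ± 0.09, Egr1 by 0.50 ± 0.06 and Atf3 by 0.41 ± 0.06. The shift was 0.24 for Nrf2 targets and 0.19 for immediate early genes after normexp with the 75th percentile, and with no filter on dim probes 0.29 and 0.24. Own medians on slides 1 and 2 were 1.09 and 1.08 (p53), 0.50 and 0.45 (Nrf2) and 0.46 and 0.43 (immediate early).

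Chaperone, degradation and housekeeping sets also lay above all genes at 4 h. Heat shock chaperones stood 0.26 above (12 of 19 up, none down, 12 up adjusted over the list alone, adjusted p = 0.00753), with adjusted p = 0.552 with an estimated correlation and 0.340 after normexp with the 75th percentile. Hspa1a rose by 1.61 ± 0.06, Bag3 by 0.58 ± 0.08 and the cochaperone gene Dnajb1 by 0.40 ± 0.08. Autophagy and lysosome genes stood 0.27 above (13 of 21 up, none down, 13 up adjusted over the list alone, adjusted p = 0.00183), with adjusted p = 0.442 with an estimated correlation and 0.162 after normexp with the 75th percentile. Gabarapl1 rose by 1.02 ± 0.05, Sqstm1 by 0.84 ± 0.10 and the initiating kinase gene Ulk1 by 0.60 ± 0.09. Ribosomal protein genes stood 0.30 above (34 of 37 up, none down, 37 up adjusted over the list alone, adjusted p = 1.25e-06), with adjusted p = 0.582 with an estimated correlation and 0.0539 after normexp with the 75th percentile. Rpl6 rose by 0.46 ± 0.06. Proteasome genes stood 0.25 above (19 of 31 up, none down, 23 up adjusted over the list alone, adjusted p = 0.000103), with adjusted p = 0.558 with an estimated correlation and 0.229 after normexp with the 75th percentile. Psmd1 rose by 0.46 ± 0.05 and Psmb2 by 0.43 ± 0.06. Respiratory chain genes stood 0.19 above (18 of 36 up, none down, 18 up adjusted over the list alone, adjusted p = 0.000483), with adjusted p = 0.546 with an estimated correlation. Their shift was -0.04 after normexp with the 75th percentile (adjusted p = 0.526), and their own median was -0.004 with no scaling. For heat shock and respiratory chain genes the adjusted p was 0.0561 and 0.0590 after quantile normalization, 0.0585 and 0.0587 with no scaling, and 0.0511 and 0.0553 after normexp with quantile, and for respiratory chain genes 0.0527 after spike-in scaling. Cox6b1 rose by 0.51 ± 0.06. The shifts were 0.02 (heat shock), 0.13 (autophagy), 0.07 (ribosomal) and 0.02 (proteasome) after normexp with the 75th percentile. For these and respiratory chain genes in turn they were 0.13, 0.11, 0.10, 0.15 and 0.11 after quantile normalization, 0.14, 0.10, 0.09, 0.14 and 0.11 after normexp with quantile, and 0.11, 0.12, 0.15, 0.09 and 0.03 with no filter on dim probes. Own medians on slides 1 and 2 were 0.35 and 0.32 (heat shock), 0.33 and 0.35 (autophagy), 0.39 and 0.36 (ribosomal), 0.33 and 0.28 (proteasome) and 0.27 and 0.26 (respiratory chain).

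Endothelial markers stood 1.22 above all genes at 4 h (3 of 8 up and none down, the same adjusted over the list alone, adjusted p = 0.0264), with adjusted p = 0.356 with an estimated correlation. Their shift was 0.27 with only genes above background on all arrays (adjusted p = 0.275) or only such members (0.303) and 0.19 after normexp with quantile (0.0710). The adjusted p was 0.0646 with no filter on dim probes and 0.0670 without 4 h replicate 2, and their own median was 1.04 on slide 1 and 1.12 on slide 2. Vwf rose by 2.22 ± 0.07 and Robo4 at least 3.31-fold. Pecam1 also passed the test and is counted among those up, but it was not well above background in untreated or 4 h cells, so its rise rests on signals at background. Markers of macrophages (adjusted p = 0.554), epithelium (0.343), neural cells (0.888), muscle (0.364), erythroid cells (0.364), adipocytes (0.603), bone and cartilage (0.451) and fibroblasts (0.810) did not pass at 4 h. Zfp genes no longer lay below all genes (96 of 277 up, 25 down, 97 and 25 adjusted over the list alone, adjusted p = 0.0748). Interferon response genes (9 of 22 up, 7 down, adjusted p = 0.685), FoxO targets (6 of 16 up, 6 down, adjusted p = 0.528), hypoxia genes (adjusted p = 0.554) and MAP kinase feedback genes (8 of 14 up, 1 down, adjusted p = 0.0677) did not pass as lists. The other antioxidant enzymes (adjusted p = 0.0578, 0.0148 with the slide as a block) and matrix genes (0.0919, 0.0470 with the block) did not pass. The same held for NF-kB inflammatory genes (0.0578, 0.0471 with the block), TGF-beta and BMP targets (0.0903, 0.0471 with the block) and splicing factor genes (0.0748, 0.0477 with the block).

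Of the other genes chosen in advance, Mt1 rose at 4 h by 0.50 ± 0.14 (0.33 on another probe), Ccl2 rose by 0.47 ± 0.06 and Trib3 fell by 0.58 ± 0.07. Ddit3 (-0.08 ± 0.10, adjusted p = 0.557) and Il6 (0.01 ± 0.06, adjusted p = 0.907) did not pass. The Ddit3 value was 0.03 without 4 h replicate 2, and the Il6 value was -0.09 after quantile normalization, -0.15 after median centring, -0.06 after normexp with quantile, -0.25 with no scaling and -0.25 after spike-in scaling, where it passed (adjusted p = 0.0430). In all, 4247 genes rose and 3172 fell at 4 h, 1136 and 455 of them at least 2-fold, and 438 of those that rose were not above background in untreated cells. All 7419 moved the same way on both slides, which the test again requires of any call. With the slide as a block 5366 rose and 3937 fell. Within slide 1, 1318 genes were at least 2-fold higher and 681 lower, and within slide 2, 1349 and 579. The split was 3231 and 3820 after quantile normalization, 2282 and 4107 after median centring, 1765 and 5458 with no scaling, 3359 and 4029 after normexp with quantile, and 1984 and 6180 after spike-in scaling. Without untreated replicate 1 there were 4430 calls and without untreated replicate 2 there were 4347, and 2379 were called after normexp with the 75th percentile. Named genes that did not pass with no scaling were Atf3, Ccl2, Cox6b1, Dnajb1, Egr1, Fosb, Gclm, Mt1, Nqo1, Psmb2, Psmd1 and Rpl6; of these Atf3, Dnajb1, Gclm, Mt1, Nqo1 and Psmb2 also lost the call after median centring and after spike-in scaling, and Psmd1 after spike-in scaling. After normexp with the 75th percentile the calls of all these but Gclm were lost, as were those of Bag3, Cdc45, Mutyh, Pecam1, Pms1, Sqstm1, Ulk1 and Xist. Mt1 and Rpl6 also lost it after quantile normalization and after normexp with quantile, Dnajb1 after the first and Fosb after the second, and Dnajb1, Fosb, Gclm and Mt1 with no filter on dim probes. With 1 array left out Dnajb1, Fosb, Gclm, Mt1 or Nqo1 no longer passed, with only the 4 arrays compared Mt1 did not, and with the mean of a gene's probes Slc7a11 and Xist did not.

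**Figure D1:**
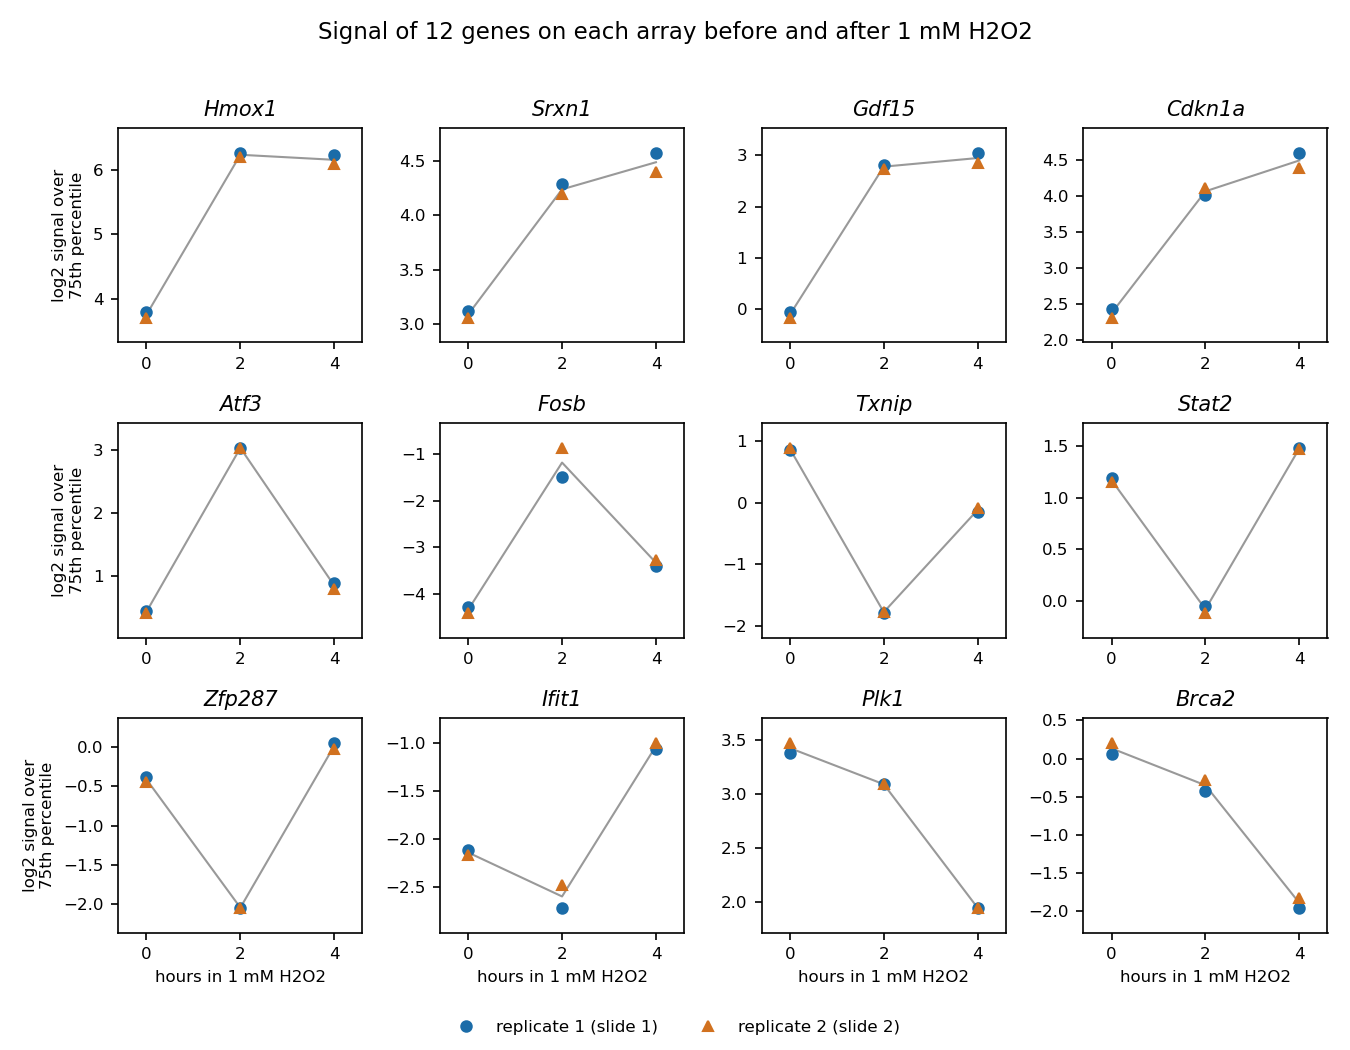
Signal of 12 genes on each of the 6 arrays, as log2 of the processed signal over the array's 75th percentile, against hours in 1 mM H2O2; points are single arrays, marked by replicate, and lines join the group means. Hmox1, Srxn1, Gdf15 and Cdkn1a were higher at 2 h and 4 h, Atf3 and Fosb peaked at 2 h, Txnip, Stat2 and Zfp287 were lowest at 2 h, and Plk1 and Brca2 were lowest at 4 h.

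**Figure D2:**
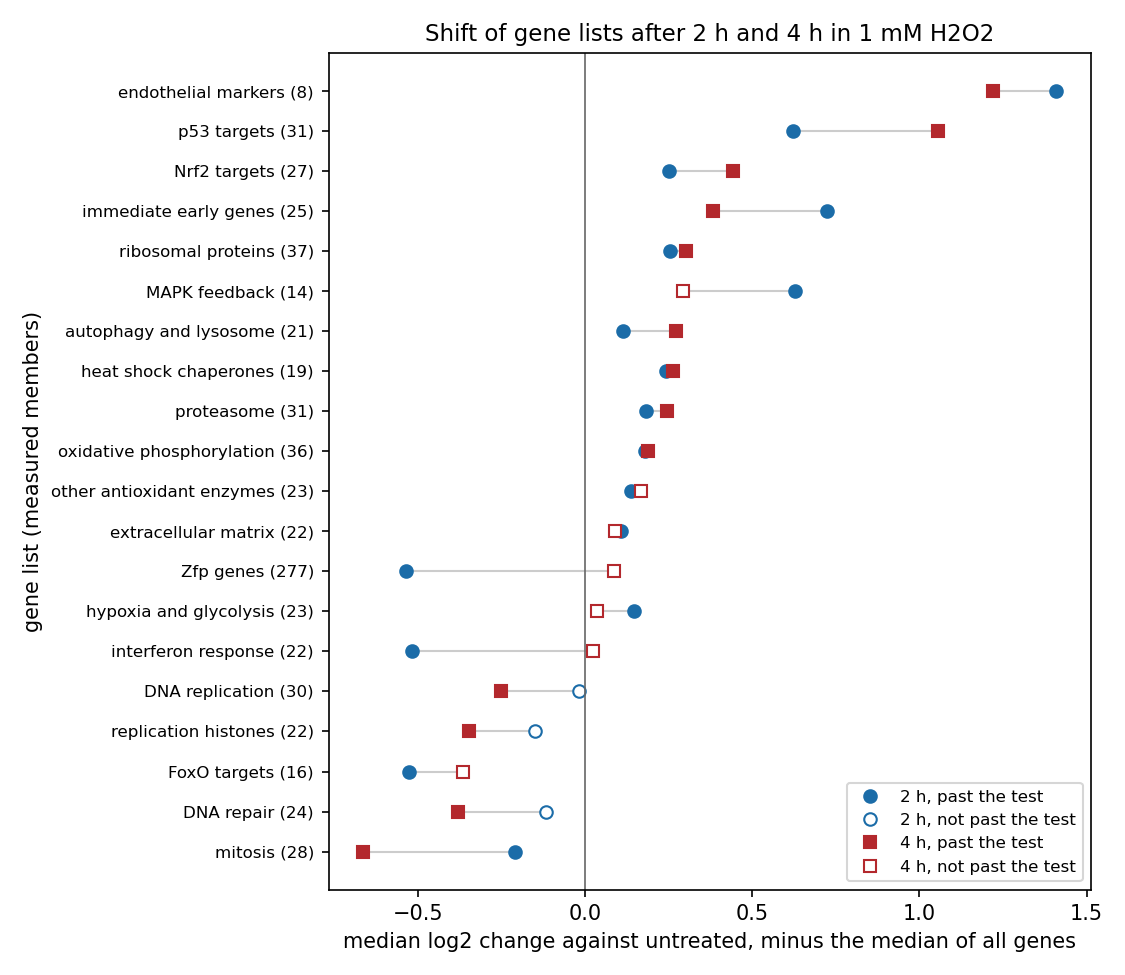
Median log2 change of each gene list that passed the camera test at 2 h or 4 h, minus the median of all genes, with the number of measured members in brackets; circles are 2 h, squares 4 h, and filled symbols passed the test. At 2 h Zfp genes lie at -0.54 and p53 targets at 0.62, and at 4 h mitosis genes lie at -0.66 and p53 targets at 1.05; extracellular matrix genes at 2 h lie at 0.11 here but at -0.05 after quantile normalization, and respiratory chain genes at 4 h at 0.19 here but at -0.04 after normexp with the 75th percentile.

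The third comparison tested the difference between 4 h and 2 h directly, without the untreated arrays entering the contrast. Immediate early genes fell back, 0.28 below all genes (13 of 25 down, 2 up, 15 and 3 adjusted over the list alone, adjusted p = 0.00336), with adjusted p = 0.287 with an estimated correlation. Egr4 and Nr4a1, inducible transcription factors, fell by 2.89 ± 0.08 and 2.11 ± 0.07, Atf3 fell by 2.19 ± 0.06, and Fosb fell by 2.16 ± 0.22. Against untreated cells at 4 h, Egr4 and Nr4a1 had -0.39 and -0.89, while Atf3 and Fosb had 0.41 and 1.01. Stmn4, a neuronal microtubule regulator, fell by 2.27 ± 0.07 (adjusted p = 0.00164). Among genes with a gene symbol above background on all 4 arrays compared, the largest rises were in Svop, a synaptic vesicle protein (2.49 ± 0.14, adjusted p = 0.00183, 1.55 on another probe), Zxdc (2.28 ± 0.06, 1.27 on its other probe) and Lipt1 (2.18 ± 0.09). Zfp genes rose by 0.65 relative to all genes (170 of 277 up, 12 down, 185 and 16 adjusted over the list alone, adjusted p = 1.84e-25, and adjusted p = 0.0189 with an estimated correlation). Among them were Zfp287 (2.07 ± 0.06) and Zfp454 (at least 1.87-fold from below background).

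Interferon response genes rose by 0.52 relative to all genes between 2 h and 4 h (12 of 22 up, none down, 12 up adjusted over the list alone, adjusted p = 6.20e-06), with adjusted p = 0.287 with an estimated correlation. The antiviral genes Mx2, Rsad2 and Ifit1 rose by 1.63 ± 0.10, 1.59 ± 0.13 and 1.56 ± 0.10, and Stat2 by 1.56 ± 0.06. NF-kB inflammatory genes rose by 0.34 relative to all genes (10 of 19 up, 3 down, 11 and 3 adjusted over the list alone, adjusted p = 0.0118), with adjusted p = 0.287 with an estimated correlation and 0.0704 with no filter on dim probes. The chemokine genes Cxcl1 and Cxcl5 rose by 0.87 ± 0.19 and 0.84 ± 0.08 and the adhesion gene Icam1 by 0.79 ± 0.07. At 2 h this list had not differed from all genes (7 of 19 up, 4 down, adjusted p = 0.975). Targets of p53 rose by a further 0.41 (15 of 31 up, 1 down, the same adjusted over the list alone, adjusted p = 8.55e-06), with adjusted p = 0.219 with an estimated correlation. Cd80 rose by 1.08 ± 0.05 on its brightest probe, with 0.05 on the other, and the death receptor gene Fas by 0.95 ± 0.06, while another probe of Fas gave 1.54 at 2 h and 1.12 at 4 h against untreated cells. Nrf2 targets rose by 0.16 (4 of 27 up, 1 down, 3 and 1 adjusted over the list alone, adjusted p = 0.0323), with adjusted p = 0.416 with an estimated correlation. Their shift was -0.02 after normexp with the 75th percentile (adjusted p = 0.799) and 0.07 with no filter on dim probes (0.134), and the adjusted p was 0.0501 with only genes above background on all arrays. Osgin1 rose by 0.77 ± 0.10 (0.08 on 1 of 2 other probes) and the carbonyl reductase gene Cbr3 by 0.60 ± 0.08. FoxO targets rose by 0.15 (7 of 16 up, 1 down, 7 and 2 adjusted over the list alone, adjusted p = 0.0434), with adjusted p = 0.314 with an estimated correlation and 0.0579 with the slide as a block. With the preset correlation it was 0.0844 after normexp with the 75th percentile, 0.0976 with no filter on dim probes (shift 0.06) and 0.0575 with only genes above background on all arrays. The members that rose included Txnip (1.66 ± 0.05), Ccng2 (1.21 ± 0.06) and Fbxo32 (1.18 ± 0.20). Shifts after normexp with the 75th percentile were 0.18 for NF-kB, 0.23 for p53 and 0.28 for FoxO genes, and that of interferon genes was 0.32 after normexp with quantile. The FoxO shift was 0.36 with every probe and 0.36 without 4 h replicate 1. Leaving out 1 array ended the Nrf2 call (adjusted p = 0.0719 without 2 h replicate 2 and 0.0815 without 4 h replicate 1) and the FoxO call (0.0834 without 2 h replicate 1 and 0.0569 without 4 h replicate 2).

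Between 2 h and 4 h mitosis genes fell by 0.45 relative to all genes (25 of 28 down, 1 up, 27 and 1 adjusted over the list alone, adjusted p = 8.07e-09), with adjusted p = 0.287 with an estimated correlation. Plk1 fell by 1.15 ± 0.06, the spindle motor gene Kif11 fell by 0.94 ± 0.08, Cenpf fell by 0.89 ± 0.06 and Mki67 fell by 0.89 ± 0.06. DNA replication genes fell by 0.14 (13 of 30 down, 1 up, 15 and 1 adjusted over the list alone, adjusted p = 0.00896), with adjusted p = 0.310 with an estimated correlation. Their shift was -0.32 after normexp with the 75th percentile, -0.24 with no filter on dim probes and -0.09 with the mean of a gene's probes. Cdc45 fell by 0.59 ± 0.09 and the replication complex gene Gins1 fell by 0.52 ± 0.07. DNA repair genes fell by 0.21 (11 of 24 down, 1 up, the same adjusted over the list alone, adjusted p = 0.00881), with adjusted p = 0.287 with an estimated correlation and 0.0994 with the mean of a gene's probes. Brca2 fell by 1.54 ± 0.09, Mutyh fell by 0.71 ± 0.07 (-0.10 on another probe above background) and Fancd2, which repairs crosslinks, fell by 0.56 ± 0.06 on the probe above background (0.04 with the mean of its probes). Own medians on slides 1 and 2 were -0.33 and -0.34 (immediate early), 0.54 and 0.59 (Zfp), 0.55 and 0.31 (interferon) and 0.29 and 0.23 (NF-kB). They were 0.33 and 0.32 (p53), 0.11 and 0.05 (Nrf2), 0.13 and 0.15 (FoxO), -0.55 and -0.57 (mitosis), -0.21 and -0.24 (replication) and -0.25 and -0.29 (repair).

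Between 2 h and 4 h 2310 genes rose and 2839 fell, 591 and 397 of them at least 2-fold. All 5149 moved in the same direction on both slides, which the test requires of any call. With the slide as a block 2855 rose and 4015 fell. Within slide 1, 750 genes were at least 2-fold higher and 643 lower, and within slide 2, 725 and 611. The split turned to more rises than falls under several settings, with 2232 and 1753 after median centring, 2240 and 1586 with no scaling, 776 and 246 after normexp with the 75th percentile, and 3838 and 1280 after spike-in scaling. It was 1416 and 1094 with no filter on dim probes and 1997 and 1977 with the mean of a gene's probes. Leaving out 1 array turned it as well, with 1318 and 1043 of 2361 calls without 2 h replicate 1, 1371 and 1088 of 2459 without 2 h replicate 2, 1652 and 1603 of 3255 without 4 h replicate 1, and 1581 and 1325 of 2906 without 4 h replicate 2. With the mean of a gene's probes Cd80, Fas, Kif11, Mutyh, Rsad2 and Txnip did not pass, and with no filter on dim probes Cdc45, Cxcl1 and Fbxo32 did not. After normexp with the 75th percentile Brca2, Cbr3, Cdc45, Cxcl1, Fancd2, Fosb, Gins1, Icam1, Kif11, Mutyh and Zfp454 lost the call, and with 1 array left out Cbr3, Cdc45, Cxcl1, Fbxo32 or Gins1 did. The remaining lists did not pass: with the slide as a block TGF-beta and BMP targets (adjusted p = 0.0753) had 0.0232 and autophagy genes (0.0563) had 0.0264.

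The changes at 2 h and 4 h were then set against each other. Across genes, which are not independent replicates, they correlated with r = 0.805, against 0.505 when unchanged groups were simulated against the same untreated arrays, and with a covariance of 0.564 against a simulated 0.0221. The same sign was seen in 73.6% of genes, against a simulated 66.7%. Of the genes called at both times 2975 rose at both, 1323 fell at both and 325 went in opposite directions, while independent lists of these sizes would share 1012 rises and 487 falls. The untreated group could not be split with 2 arrays in each part, so part of the excess may come from the shared controls. Of the genes that fell at 2 h, 1369 rose between 2 h and 4 h, including 132 Zfp genes, and 383 fell again. Of the genes that rose at 2 h, 866 fell afterwards and 301 rose again. Both steps use the 2 h arrays with opposite sign, which favours opposite moves, and no value for unchanged groups was computed for these counts. Zfp111 and Zfp287, for example, had changes of -2.07 and -1.64 at 2 h and of -0.14 (adjusted p = 0.407) and 0.43 (adjusted p = 0.00670) at 4 h.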

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

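Of the tests weighed here, those of cross-hybridisation and of the expression level and length of Zfp genes were planned before their results were seen, and those of a general gain of dim probes, of neighbouring genes and of the spike-in controls were chosen after seeing the result. The 3 patterns were chosen for weighing from the comparisons with untreated cells. The genes and lists in the closing paragraph were picked out because the effects of 2 h and 4 h differed by the limma or camera test of 4 h against 2 h.

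A first pattern is the 466 genes that were not above background in untreated cells and rose at least 2-fold to above it at 2 h, such as Vil1 and Ampd1; 400 of them also rose at 4 h. If single probes cross-hybridised, other probes of the same genes would stay low. Of these, 41.1% (53 of 129, 95% interval 32.5% to 50.1%) gained at least 1, against 13.3% of dim probes of other genes. The 129 were not limited to dim probes, so the shares are not strictly alike. The share lies just above the 40% set in advance as counting against this explanation. Its interval reaches below 40%, so the explanation is neither shown nor excluded. A general gain of dim probes, from genomic DNA or background, stays open, since their median change of 0.26 was set by the floor of the scanner software for the 85.0% that remained below background at 2 h. That change is also relative to the 75th percentile, which itself changed by -0.337 at 2 h. On slides 1 and 2, negative control spots had mean signals of 6.67 and 5.16 (untreated), 5.98 and 4.03 (2 h) and 8.55 and 8.07 (4 h), so they showed no gain of background at 2 h. If transcription ran past the end of an expressed gene upstream, a bright upstream neighbour on the same strand within 100 kb should be more frequent. It was, at 48.4% of 463 members against 17.5% of 12818 other dim probes. Bright neighbours were also more frequent among members downstream on the same strand (30.02% against 19%). The same held on the opposite strand, upstream (32.83% against 15.1%) and downstream (34.99% against 21.83%). With all orientations in the same model, the odds ratio for a same-strand upstream neighbour was 3.53 (95% interval 2.88 to 4.32). In that model it was lower for a same-strand neighbour downstream (1.17) and an opposite-strand neighbour upstream (1.69) or downstream (1.29). The interval takes probes as independent, although a gene can have several of the other probes. These values are what read-through from upstream genes could give, but the arrays hold no probes between genes, and induction of the genes themselves stays open.

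A second pattern is the fall of Zfp genes at 2 h, with a median of -0.42, and their return by 4 h. Their low level does not account for it, since 10000 random lists matched on level had medians from 0.01 to 0.11 in their middle 95%, and none was as low. Their gene length does not either, with a median of -0.43 against 0.08 to 0.16 in lists matched on length; across all genes the change had a Spearman correlation with length of -0.12 at 2 h and -0.15 at 4 h. Short-lived transcripts during a pause in transcription could give such a pattern, but no half-lives were used here, so this was not tested.

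The last pattern is the lower 75th percentile of the treated arrays, by -0.34 at 2 h and -0.26 at 4 h in log2. If yield in labelling or scanning were lower, the spike-in controls should fall as much, but they changed by 0.12 at 2 h and 0.002 at 4 h, with replicates apart by 0.03 and 0.14. This argues against lower yield in these steps, and against an effect of slide position common to all probes, provided that equal amounts of control RNA were added, which is not given in the sources used here. Less messenger RNA in the labelled total RNA could give the shift, which was not tested.

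Named genes with a lower level at 4 h than at 2 h, by more than 1 in log2, were Egr4 (-2.89), Stmn4 (-2.27), Atf3 (-2.19), Fosb (-2.16), Nr4a1 (-2.11), Brca2 (-1.54), Pms1 (-1.22), Plk1 (-1.15) and Stra8 (-1.03). Those lower by 1 or less were Sapcd2 (-0.99), Kif11 (-0.94), Vil1 (-0.90), Cenpf (-0.89), Mki67 (-0.89), Robo4 (-0.71), Mutyh (-0.71), Rasgef1a (-0.71), Aurka (-0.66), Vegfa (-0.65), Cdc45 (-0.59), Depdc1b (-0.59), Fancd2 (-0.56), Gins1 (-0.52), Il6 (-0.48), Pole (-0.47), Phlda1 (-0.46), Junb (-0.42) and Brca1 (-0.35). Named genes with a higher level at 4 h than at 2 h, by more than 1, were Svop (2.49), Zxdc (2.28), Lipt1 (2.18), Trim13 (2.13), Zfp287 (2.07), Zfp111 (1.94), Txnip (1.66), Col20a1 (1.66), Mx2 (1.63), Rsad2 (1.59), Ifit1 (1.56), Stat2 (1.56), Irf1 (1.55), Rtp4 (1.43), Ccng2 (1.21), Fbxo32 (1.18) and Cd80 (1.08). Those higher by 1 or less were Fas (0.95), Tube1 (0.91), Cxcl1 (0.87), Cxcl5 (0.84), Icam1 (0.79), Osgin1 (0.77), Lman1l (0.61), Ulk1 (0.60), Cbr3 (0.60), Pmaip1 (0.59), Dnajb1 (0.59), Hspa1a (0.49), Fosl1 (0.46), Cdkn1a (0.43), Vwf (0.41), Ccng1 (0.39) and Gabarapl1 (0.33). On other probes above background the difference was 0.76 for Rasgef1a and -0.42 for Fas, of opposite sign, and 0.05 for Cd80, 0.08 for Osgin1, -0.10 for Mutyh, -0.26 for Vegfa, 1.27 for Zxdc and 1.55 for Svop. Pecam1, below background at 4 h, and Zfp454, below background at 2 h, had differences of -0.97 and 2.22, which rest on signals below background and so give no size; Zfp454 rose at least 1.87-fold. Among lists, relative to all genes, Zfp genes (0.65), interferon response genes (0.52), p53 targets (0.41), NF-kB inflammatory genes (0.34), Nrf2 targets (0.16) and FoxO targets (0.15) were higher at 4 h than at 2 h, and mitosis (-0.45), immediate early (-0.28), DNA repair (-0.21) and DNA replication genes (-0.14) lower.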

How the results depend on the processing

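Of the alternatives, spike-in scaling was chosen after seeing the data and the others before. For 40 list calls and 161 named-gene results, the alternatives other than fry and leaving out an array were tallied, with replicate and slide block counted once. Direction and side of the threshold were kept in 569 list values and 2214 gene values. The call was lost in the same direction in 107 and 143, 17 gene values gained it, and 4 and 24 changed direction. For lists, direction is the side on which camera placed them, so a list whose median shift changed sign can count as the same direction. Some settings could hardly differ, since the deposited table holds the same signal and, with every probe, each named gene was read from the same probe. The deposited table gave 7416 calls at 4 h and the same calls elsewhere. With the slide as a replicate block 9076, 9303 and 6870 genes (2 h, 4 h, 4 h against 2 h) and 17, 18 and 11 lists were called, and the replicate block changed no call other than those in the report. A block by scan date was not run, since all arrays had the same date.

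Counts of changed genes at 2 h, 4 h and 4 h against 2 h were 1566, 2379 and 1022 with normexp and the 75th percentile; 4045, 4573 and 2510 with no filter, where more genes were tested; 3185, 3721 and 2121 at adjusted p under 0.01; and 1839, 1591 and 988 at 2-fold or more. Spike-in scaling called 10655 genes at 2 h. Lists called were 10 after quantile normalization and 11 after spike-in scaling at 2 h, 20 after normexp with the 75th percentile and 16 after spike-in scaling for 4 h against 2 h, 1, 0 and 1 with an estimated correlation, and 32, 32 and 22 with fry, which does not compare with other genes. Leaving out 1 array gave 3600 to 6129 genes and 14 to 17 lists at 2 h, 4347 to 6144 and 11 to 14 at 4 h, and 2361 to 4199 and 9 to 13 for 4 h against 2 h, with fewer arrays.

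Directions changed in these results. At 2 h matrix genes had a shift of -0.049 (quantile) and -0.063 (normexp with quantile). After spike-in scaling camera placed them and the other antioxidant enzymes on the lower side of all genes, although their median shifts were 0.108 and 0.137. After normexp with the 75th percentile the median shift was -0.04 for respiratory chain genes at 4 h and -0.023 for Nrf2 targets at 4 h against 2 h. Camera kept both of these lists on the upper side. Col1a1 at 2 h had -0.042 (quantile), -0.011 (no scaling), -0.025 (normexp with quantile) and -0.126 (spike-in). Il6 at 4 h had -0.089 (quantile), -0.146 (median), -0.25 (no scaling), -0.057 (normexp with quantile) and -0.251 (spike-in), and from -0.005 (without 4 h replicate 2) to 0.026 with 1 array left out, with -0.001 without untreated replicate 1. Ddit3 at 4 h ranged from -0.199 (without 4 h replicate 1) to 0.032 (without 4 h replicate 2). With no scaling Nqo1 and Mt1 at 2 h had -0.067 and -0.053. After spike-in scaling, values at 2 h were Gclm -0.034, Nqo1 -0.182, Mt1 -0.168, Sod1 -0.07, Prdx6 -0.07, Uqcrb -0.01, Cox6b1 -0.076, Rpl6 -0.02, Rps20 -0.026 and Psmb2 -0.017. The mean of a gene's probes gave Sod1 -0.11 at 2 h, Pole 0.099 at 4 h and Fancd2 0.04 for 4 h against 2 h, by including dimmer probes. Median centring, no scaling and spike-in scaling each move all genes of a comparison by the same amount. This gives the reversals of single genes under them. Spike-in scaling lowered every gene's change by 0.452 at 2 h and by 0.262 at 4 h. No scaling moved every gene's change by -0.337 at 2 h and by -0.26 at 4 h. For the other changes the cause was not tested.

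The signal over background sets which genes were tested: between 57.3% and 68.0% of spots passed on each array, and the 2 arrays per group limit the precision of each change.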

Other observations

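Gene families that share a name stem were tested with camera after seeing the data, 83 families of at least 15 measured genes, so these results are hypotheses. At 2 h 17 passed and at 4 h 12 passed, none with an estimated correlation; those that passed under all 7 scalings are given here. Transfer RNA methyltransferase genes (Trmt) stood 0.54 below all genes at 2 h (11 of 17 down, none up, adjusted p = 0.000706), with adjusted p = 0.495 with an estimated correlation. Cilia and flagella genes (Cfap) stood 0.20 above at 2 h (7 of 17 up, 1 down, adjusted p = 0.0145), with adjusted p = 0.495 with an estimated correlation. At 4 h peroxisome assembly genes (Pex) stood 0.67 below (10 of 16 down, 2 up, adjusted p = 0.00207), with adjusted p = 0.698 with an estimated correlation. Centrosome genes (Cep) stood 0.41 below (17 of 35 down, 3 up, adjusted p = 0.00207), with adjusted p = 0.698 with an estimated correlation. Integrator complex genes (Ints) stood 0.36 below (7 of 15 down, 1 up, adjusted p = 0.00985), with adjusted p = 0.698 with an estimated correlation. Large ribosomal subunit genes (Rpl), which overlap the ribosomal list of the report, stood 0.32 above (38 of 47 up, none down, adjusted p = 1.70e-06), with adjusted p = 0.698 with an estimated correlation. The size of the Rpl rise depended on the scaling, with an own median of 0.39 here and 0.11 after quantile normalization.

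Several lists fixed before the data were examined did not pass in either comparison with untreated cells. Targets of ATF4, which directs amino acid and stress responses, had 10 of 27 up and 2 down at 2 h (adjusted p = 0.180) and 8 up and 2 down at 4 h (adjusted p = 0.419). Chaperones of the endoplasmic reticulum had adjusted p = 0.365 and 0.472, metal response genes 0.438 and 0.233, splicing factor genes 0.151 and 0.0748, ribosome biogenesis genes 0.951 and 0.995, cytoskeletal targets of SRF and YAP 0.634 and 0.316, cholesterol synthesis genes 0.269 and 0.175, apoptosis regulators 0.882 and 0.548, and clock genes 0.853 and 0.848. At 2 h TGF-beta and BMP targets had adjusted p = 0.853, DNA replication genes 0.795, replication histone genes 0.119 and DNA repair genes 0.228. For NF-kB genes at 2 h the median lay 0.06 above all genes while camera placed the list on the lower side, and for SRF and YAP targets (0.07), TGF-beta and BMP targets (0.04) and apoptosis regulators (0.05) the median and the test also differed in sign; none of these passed.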
